A study of Sciaenops ocellatus with 18 samples.

How the data were processed

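Livers and spleens of juvenile red drum (Sciaenops ocellatus), a marine fish, were profiled by RNA sequencing after exposure to oil, to the fish pathogen Vibrio anguillarum, to both or to neither. The labels give 18 libraries in 7 groups: 3 libraries in each of 4 liver groups and 2 in each of 3 spleen groups, with no oil only spleen group analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

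Per the labels' protocols, RNA was extracted with an RNeasy kit and polyA libraries were built with a TruSeq Stranded mRNA kit. The submitters' processing notes name CASAVA and FastQC. The aligner, the quantification tool, the reference genome and its annotation are not given in the sources used here. The deposited values are in TPM, per the file headers, with 1 file per library. Each library lists 26745 features whose TPM values sum to 1e+06. Of these, 10263 carry a gene symbol, 15349 only a locus number and 1133 a tRNA name. The files do not pair locus numbers with gene names, so no name was given to them. No 2 libraries held identical values.

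TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval was computed. TPM is a share of a fixed total: when a few abundant transcripts take less of a library, every other transcript reads higher. The share taken by the 10 most abundant features is therefore given with the data, and every count of changed genes was repeated after median-of-ratios scaling, in which each library is divided by the median ratio of its genes to their geometric means. Reads shared between close gene copies, which are common in fish, could be split between them in ways the files do not show.

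The design had been written for counts, with a fallback for normalized values, and the fallback was used. TPM values were transformed as log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. Features at 1 TPM or more in at least 3 libraries (liver) or 2 libraries (spleen, and both tissues together) were tested. limma 3.58.1 in R 4.3.3 was fitted with a mean per group and empirical Bayes moderation with trend and robust options. All 12 liver libraries entered 1 fit, all 6 spleen libraries another, and all 18 a fit for the difference between tissues. Tests were 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 12 comparisons were the single contrasts, the liver interaction and main effects of oil and pathogen, and the pathogen effect in spleen minus that in liver. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

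A set of 33 gene lists (pathways, complexes and cell types) was matched by symbol without regard to case. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other tested genes. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists of a comparison. Camera can give a list as lower than other genes while its own median is above 0. With an estimated correlation, 2 of the 141 list calls over all comparisons held, both in the difference between tissues.

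The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are those past the threshold with a symbol, at least 1 TPM in the higher group and no overlap between the libraries of the groups, taking the 10 largest changes per direction against control or the 5 largest otherwise. Up to 4 members per described list with the smallest p were added, with ahrr and 9 other response genes wherever they were measured. Of these 10 only ahrr matched a symbol, and the others were not analysed here. With fewer than 3 genes past the threshold, the 3 with the smallest p were given as values. A few locus numbers and marker genes of doubtful libraries were singled out after their values were seen.

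The procedure was tested on simulated data with 200 changed genes. For oil only against control liver, 6.35%, 79.7% and 90.4% of genes changed 2-, 4- and 8-fold were recovered among 12025 genes, with 11 false calls among 132. For oil and pathogen against pathogen only liver, the shares were 4.55%, 70.3% and 91.4%, with 3 false calls among 115. For oil and pathogen against pathogen only spleen no changed gene was recovered among 14648 genes, and for the difference between tissues 12.9% of the 8-fold changes were recovered among 15784 genes. Alternatives covered the pseudocount, the filter, the scaling, a replicate block, the groups in the fit and leaving out each library. Others, including quantile normalization, sample quality weights and the level of cpb1 as a covariate, were added after seeing the data.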

Results

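The study asked how liver and spleen transcripts of juvenile red drum respond to oil, to a bacterial pathogen and to both together. Oil was given for 5 days as a high energy water accommodated fraction, which is seawater mixed vigorously with oil, here from the Macondo well, at 695.188 µg/L. The pathogen was given for 1 hour, 24 hours before sampling. Its dose was 11000000 cfu/mL alone and 14600000 cfu/mL with oil, so the pathogen groups differ in dose as well as in oil. The 12 liver libraries held 8958 to 13945 features at 1 TPM or more, and the 6 spleen libraries 7267 to 14401. The 10 most abundant features took 35.1% ± 3.69 (SD, n = 3) of the TPM in control liver, against 28.0% ± 1.71 in oil only liver. The share was 30.4% ± 4.51 in pathogen only liver and 29.4% ± 0.992 in liver given both. In spleen it was 36.7% ± 14.7 in control, 32.2% ± 3.32 with pathogen only and 15.5% ± 6.41 with both (SD, n = 2 each).

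Marker genes of cell types set 3 libraries apart. In the library labelled Control Spleen replicate 1, hepatocyte markers averaged 6.53 log2(TPM + 1), against 0.70 to 1.56 in the other spleen libraries and 6.94 to 8.76 in liver. Its B cell markers averaged 1.08, against 3.51 to 5.17 in the other spleen libraries, and cd79a, a part of the B cell receptor, was listed at 0. Its median Spearman correlation across genes was 0.829 with the liver libraries and 0.730 with the other spleen libraries. Pathogen Only Liver replicate 2 carried gut transcripts, with a mean of 8.53 over a gut list chosen after its values were seen. That list averaged 0.323 ± 0.196 in control, 0.840 ± 0.443 in oil only and 0.734 ± 0.142 in liver given both (SD, n = 3 each). Pathogen Only Spleen replicate 1 held exocrine pancreas markers at 5.27, against 1.78 to 2.76 in the spleen libraries other than Control Spleen replicate 1, which held 7.50. The exocrine pancreas list had only 3 tested members in liver and 2 in spleen. Of its matched genes, cpb2 is made by hepatocytes and was at 239 ± 19.7 TPM in control liver. In libraries with hepatocyte transcripts the level of this list thus does not stand for pancreas alone.

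Oil alone raised proteasome genes in liver. Of 30 tested members, 28 rose and none fell, with a median log2 fold change of 2.45, or 1.85 above the median of all genes. psmd8, a lid subunit of the complex that degrades tagged proteins, went from 7.70 ± 0.103 TPM in control to 68.7 ± 30.9 in oil only liver (SD, n = 3 each), a log2 fold change of 2.88 (SE 0.41, adjusted p = 0.0049). The ATPase subunits psmc2 (2.89, SE 0.46) and psmc5 (2.61, SE 0.40) rose with it. So did the lid subunit psmd13 (2.89, SE 0.43), the core subunit psmb2 (2.28, SE 0.33) and usp14, a ubiquitin-removing enzyme bound to the proteasome (3.28, SE 0.57, adjusted p = 0.0075). Camera placed the list above other genes (adjusted p = 9.4e-19, and adjusted p = 0.96 with an estimated correlation), and 29 members passed when adjusted over the list alone. After median-of-ratios scaling 15 members still rose, with a median of 1.68. With the level of cpb1 as a covariate, chosen after the data were seen, no member passed. The median was then 2.01 with a median SE of 0.686, against 2.45 and 0.439 without it, and 65.3% of the variance of cpb1 lay between groups. The 5 subunits named here passed with each liver library left out in turn, and usp14 did not without Control Liver replicate 2 (adjusted p = 0.0562) or Oil Only Liver replicate 2 (adjusted p = 0.057).

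Heat shock proteins and chaperones also rose in oil only liver. Of 26 members 17 rose and none fell, with a median of 1.58, or 0.98 above all genes, and 23 passed adjusted over the list alone. Camera gave adjusted p = 2.2e-06, and adjusted p = 0.96 with an estimated correlation, and 3 members rose after scaling, with a median of 0.83. The mitochondrial chaperones hspd1 (2.37, SE 0.37) and hspa9 (2.30, SE 0.45), the chaperonin subunit cct2 (1.93, SE 0.42) and chordc1, a partner of HSP90 (2.15, SE 0.47), were among the rises.

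Smaller parts of the stress and metabolic lists rose as well. Of 24 oxidative stress genes 5 rose, including srxn1, which restores oxidized peroxiredoxins (2.40, SE 0.46), pgd of the pentose phosphate pathway (3.26, SE 0.69), maff (1.95, SE 0.45) and blvrb (1.27, SE 0.38). In that list 12 passed adjusted over the list alone, 2 rose after scaling, and camera did not separate it from other genes (adjusted p = 0.56). Of 11 other detoxification genes 3 rose, namely ugdh, which makes the sugar donor for glucuronidation (3.37, SE 0.71), the efflux pump abcc2 (1.81, SE 0.44) and gstz1 (1.22, SE 0.30). There 5 passed adjusted over the list alone and 1 rose after scaling (camera adjusted p = 0.48). Of 37 fatty acid oxidation genes 12 rose, among them hadha (1.54, SE 0.34) and the regulator ppargc1a (1.64, SE 0.36), but after scaling none rose, 1 fell and the median turned from 0.70 to -0.05. In that list 14 passed adjusted over the list alone (camera adjusted p = 0.34). Of 45 genes of endoplasmic reticulum (ER) stress 5 rose (median 0.78, camera adjusted p = 0.34), and none did after scaling. Of 22 hepatocyte markers 4 rose (median 0.62, camera adjusted p = 0.74), with no rise and a median of -0.18 after scaling.

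The largest named rises in oil only liver included clu (4.18, SE 1.02), pck1, the entry enzyme of gluconeogenesis (3.78, SE 1.03), and the deiodinase dio1 (3.43, SE 0.86). The peptidase dpp3 (3.12, SE 0.58), the growth factor fgf1 (3.06, SE 0.71) and tmem33 (2.90, SE 0.49) followed. slc22a16, a carnitine transporter, fell from 26.6 ± 5.81 to 2.63 ± 1.11 TPM (log2 fold change -2.95, SE 0.38, adjusted p = 0.0049). The mitochondrial folate and glycine enzymes aldh1l2 (-2.42, SE 0.47) and dmgdh (-2.27, SE 0.51) and the chemokine ccl17 (-2.02, SE 0.54) also fell. Further falls were those of fstl3 (-1.76, SE 0.32), mif (-1.47, SE 0.38), the peptidoglycan recognition gene pglyrp2 (-2.15, SE 0.58) and tnfrsf13b, a receptor on B cells (-1.32, SE 0.35). cpb1, a digestive enzyme of the exocrine pancreas, fell from 12770 ± 6438 to 2572 ± 1083 TPM (-2.24, SE 0.57, adjusted p = 0.028). Among features with a locus number only, LOC104920743 went from 55.3 ± 18.6 to 2944 ± 1720 TPM and LOC104928952 from 214 ± 124 to 6.01 ± 3.54.

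The 4 measured genes listed for the aryl hydrocarbon receptor, which binds aromatic hydrocarbons, did not pass in oil only liver. The list held 16 symbols, and the others were not analysed here. Of the 4, aip is a partner of the receptor rather than a target. ahrr was at 1.79 ± 1.70 TPM against 0.0231 ± 0.0400 (adjusted p = 0.16) and tiparp at 15.5 ± 8.67 against 3.45 ± 0.419 (adjusted p = 0.073). Adjusted over the list alone, 2 of the 4 passed.

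In all, 1415 of 12025 genes were called between oil only and control liver, 1341 higher and 74 lower. The median log2 fold change of all genes was 0.60, and median-of-ratios scaling took it to 0.03. That scaling left 168 calls, 103 higher and 65 lower, of which 134 were shared with the unscaled calls in the same direction. With the level of cpb1 as a covariate 0 genes were called. Outside the proteasome, usp14, dpp3, tmem33, ugdh, pgd, srxn1, hspd1, hspa9, chordc1, slc22a16, aldh1l2, dmgdh, ccl17, fstl3 and tnfrsf13b passed after scaling. The genes clu, pck1, dio1, fgf1, cpb1, pglyrp2, mif, cct2, maff, blvrb, abcc2, gstz1, hadha and ppargc1a did not. Oxidative phosphorylation genes had a median of 0.79, which scaling took to -0.0068. Of 48 members 7 rose, none did after scaling, and 17 passed adjusted over the list alone (camera adjusted p = 0.017, and adjusted p = 0.96 with an estimated correlation). Cell cycle genes (median 0.06, camera adjusted p = 2.1e-05) and neutrophil genes (median 0.08, adjusted p = 0.0036) lay below other genes, as did interferon genes (median 0.09, adjusted p = 0.0052) and sterol synthesis genes (median -0.07, mean 0.07, adjusted p = 5.5e-04). All 4 had adjusted p = 0.96 with an estimated correlation, no member of them fell, and the 3 medians above 0 lay below it after scaling. Leaving out single libraries gave 61 calls (without Control Liver replicate 2), 72 and 100 (without Oil Only Liver replicates 2 and 1), 230 and 780 (without Control Liver replicates 1 and 3), or 2195 and 4271 (without Pathogen Only Liver replicates 1 and 2).

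**Figure D1:**
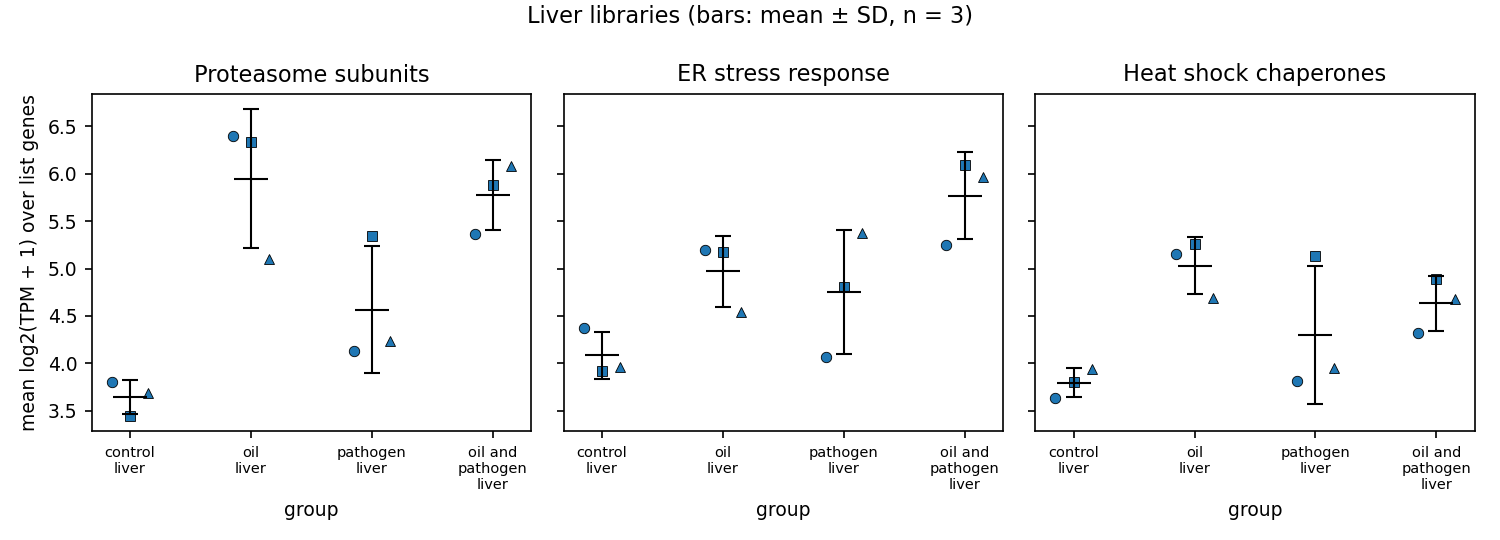
Mean log2(TPM + 1) of the proteasome, ER stress and heat shock lists in each liver library, by group. Symbols are libraries (circle, square and triangle for replicates 1, 2 and 3), bars the group mean ± SD (n = 3); proteasome genes averaged 3.65 ± 0.182 in control and 5.95 ± 0.731 in oil only liver on the TPM scale.

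Fish given both oil and pathogen showed the proteasome rise in liver together with a rise of genes of protein folding in the ER. Of 30 proteasome genes 26 rose, with a median log2 fold change of 2.18 against control, or 1.65 above all genes (camera adjusted p = 1.1e-17, and adjusted p = 0.998 with an estimated correlation). Examples were psma2 (2.97, SE 0.48), psmc4 (2.92, SE 0.44) and psmd8 (2.74, SE 0.41). Of 45 ER stress genes 24 rose and none fell, with a median of 1.40, or 0.87 above all genes (camera adjusted p = 5.8e-11, and adjusted p = 0.998 with an estimated correlation). Adjusted over the list alone, 35 ER stress and 28 proteasome genes passed. creld2, an ER stress-induced protein, went from 2.68 ± 3.20 to 73.9 ± 24.2 TPM (log2 fold change 4.64, SE 0.66, adjusted p = 0.0063). The disulfide isomerases pdia4 (4.26, SE 0.91) and pdia6 (3.46, SE 0.84), calu (4.04, SE 0.94), manf (3.63, SE 0.60), the chaperone hsp90b1 (2.49, SE 0.47) and derl1 (1.82, SE 0.36) rose as well. Without Control Liver replicate 2, creld2 did not pass (adjusted p = 0.0515). Of 26 heat shock genes 5 rose and 15 passed adjusted over the list alone (camera adjusted p = 0.030, and adjusted p = 0.998 with an estimated correlation). None of them rose after scaling, when camera gave adjusted p = 0.054.

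Parts of some immune lists rose in the same liver comparison, while none of 13 neutrophil and 14 interferon genes did. Of 10 genes that sense microbes 3 rose and of 12 macrophage genes 1 did, while 1 of 4 B cell genes fell. Of 28 genes of inflammatory cytokines and NF-kB signalling 6 rose, including tnfaip3, a brake on NF-kB (3.46, SE 0.61), map3k8 (3.58, SE 0.75), stat3 (1.76, SE 0.45) and the interleukin 6 receptor subunit il6st (1.73, SE 0.42). In that list 9 passed adjusted over the list alone, and camera gave adjusted p = 0.053. Of 14 complement genes 5 rose, among them c9 (524 ± 58.7 to 2715 ± 1012 TPM, log2 fold change 2.32, SE 0.56), cfh (1.70, SE 0.39), cfp (1.65, SE 0.42) and c6 (1.69, SE 0.44). There 10 passed adjusted over the list alone, and camera gave adjusted p = 0.21. Of 7 antigen presentation genes 4 rose, among them the proteasome activators psme1 (1.79, SE 0.38) and psme2 (1.90, SE 0.42) and the ER chaperone canx (1.58, SE 0.32). Adjusted over the list alone 6 passed (camera adjusted p = 0.012, and adjusted p = 0.998 with an estimated correlation). After scaling 1 NF-kB gene rose, tnfaip3, and no complement or antigen presentation gene did. The lectin gene dc-sign rose by 7.22 (SE 1.74) with a wide spread, 1874 ± 2548 TPM against 6.41 ± 6.66. The transcription factor egr1 (3.96, SE 0.68), tfpi2 (3.42, SE 0.50) and the metalloreductase steap4 (2.99, SE 0.45) rose too. In oil only against control liver, 4 of 7 antigen presentation, 3 of 28 NF-kB, 2 of 14 complement and 2 of 12 macrophage genes rose. Over all genes 1341 of 12025 rose there, a share near those of the NF-kB and complement lists. In the same comparison 1 of 10 microbe sensing genes and 1 of 4 B cell genes fell. The antigen presentation list shares psmb8 with the proteasome list and holds the proteasome activators psme1 and psme2. Camera did not separate the lists of these rises from other genes.

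In liver given both, dmgdh fell (257 ± 41.4 to 44.6 ± 25.2 TPM, log2 fold change -2.71, SE 0.51), as did ahcy (-2.01, SE 0.39) and aldh1l2 (-1.97, SE 0.47). slc22a16 (-2.55, SE 0.38), mif (-2.48, SE 0.38), the fructose transporter slc2a5 (-2.26, SE 0.59), klf11 (-2.24, SE 0.41) and tkt of the pentose phosphate pathway (-1.21, SE 0.37) fell too. ahrr was at 1.94 ± 1.17 TPM (adjusted p = 0.14), and 3 of the 4 genes listed for the aryl hydrocarbon receptor passed only adjusted over the list alone. Cell cycle genes lay below other genes (median 0.22, or -0.26 after scaling, camera adjusted p = 0.0052, and adjusted p = 0.998 with an estimated correlation), with no member falling.

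In all, 1205 genes were called between liver given both and control, 1143 higher and 62 lower, with a median of 0.54 over all genes. After median-of-ratios scaling the median was 0.03 and 168 were called, 98 higher and 70 lower, 135 of them shared with the unscaled calls. With the level of cpb1 as a covariate 0 genes were called. After scaling 11 proteasome genes and 1 ER stress gene, creld2, still rose, and egr1, tfpi2, tnfaip3 and every fall named here passed. The other rises named here outside the proteasome did not. Leaving out 1 library gave from 18 calls (without Control Liver replicate 2) to 3480 (without Pathogen Only Liver replicate 2), with 31 and 138 without Oil and Pathogen Liver replicates 3 and 2, and 328 and 670 without Control Liver replicates 1 and 3.

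**Figure D2:**
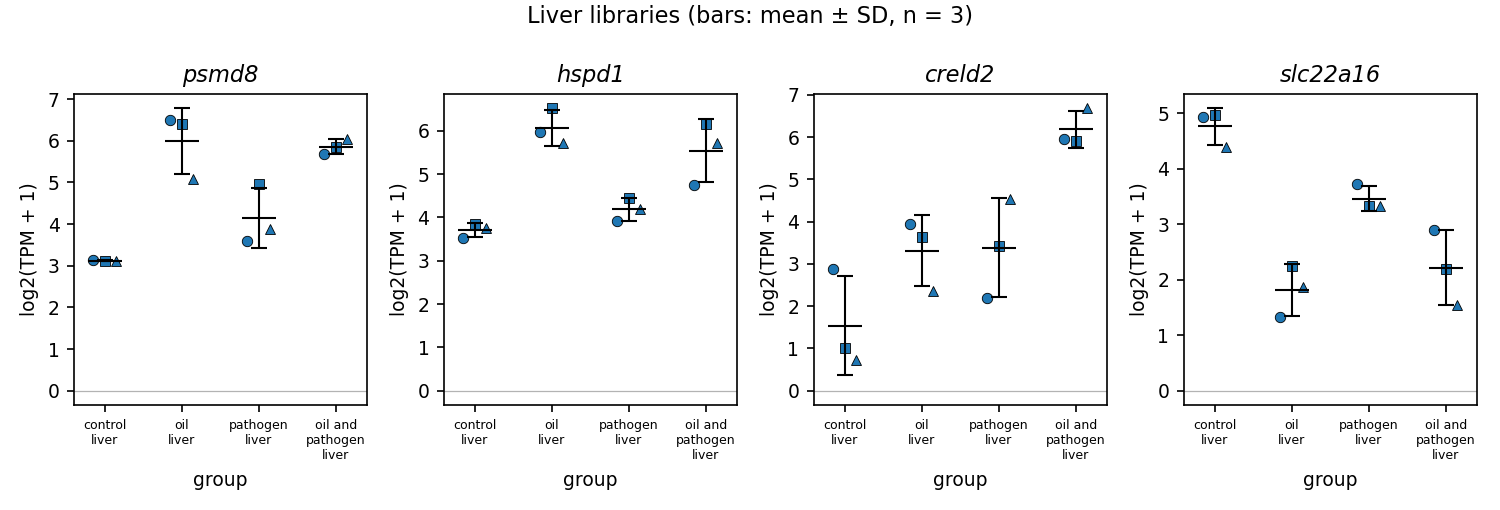
log2(TPM + 1) of psmd8, hspd1, creld2 and slc22a16 in each liver library, by group. Symbols are libraries and bars the group mean ± SD (n = 3); psmd8 lay at 7.70 ± 0.103 TPM in control and 57.3 ± 7.55 TPM in liver given both.

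The calls of these liver comparisons overlapped. Between oil only and both, each against control, 666 higher and 27 lower calls were shared and none went opposite ways. Independent lists of these sizes would share 127 higher and 0.382 lower. In 100 simulations all groups were unchanged and shared 1 simulated control group, and 0.06 higher calls were shared on average, at most 6. All libraries, controls included, were redrawn from the deviations of the 12 liver libraries from their group means. With no effect simulated few calls are expected in either list, so this count cannot show what lists of these sizes owe to shared controls. The log2 fold changes correlated across genes, which are not independent replicates, at 0.744 (simulated 0.441), with a covariance of 0.340 against a simulated 0.0930. The 3 control libraries are too few to split, so part of the excess may come from sharing them. The pathogen only comparison shared no calls with either, having none. Its fold changes correlated at 0.305 with those of oil only (simulated 0.464) and at 0.425 with those of both (simulated 0.413), with covariances 0.013 and 0.063 above the simulated values.

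The pathogen alone changed no gene past the threshold in liver at 24 hours. limma called 0 of 12025 genes, with 833 at an unadjusted p under 0.05 and a smallest adjusted p of 0.625, and also 0 after median-of-ratios scaling, with 858. The smallest p-values with a symbol were those of the signalling regulator rgs3 (6.61 ± 1.45 against 1.86 ± 0.247 TPM), dhrs7 (14.6 ± 10.2 against 3.30 ± 2.48) and immp1l (2.10 ± 0.382 against 0.320 ± 0.277), each at adjusted p = 0.625. ahrr was at 1.70 ± 2.74 against 0.0231 ± 0.0400 TPM (adjusted p = 0.625). As lists, proteasome genes (median 0.95, camera adjusted p = 1.0e-08), neutrophil genes (median 0.81, adjusted p = 0.0025) and antigen presentation genes (median 0.69, adjusted p = 0.014) lay above other genes, whose median was 0.33. With an estimated correlation these had adjusted p = 0.49, adjusted p = 0.48 and adjusted p = 0.48. No member passed over all genes, and 3 neutrophil and 3 antigen presentation genes passed adjusted over the list alone. Acute phase genes (median -0.50, adjusted p = 5.4e-14), hepatocyte genes (median -0.33, adjusted p = 2.8e-09) and sterol synthesis genes (median -0.14, adjusted p = 7.7e-06) lay below, all with adjusted p = 0.48 with an estimated correlation. ER stress genes lay above (median 0.46, camera adjusted p = 0.039, and adjusted p = 0.81 with an estimated correlation). In all, camera placed 4 lists above and 8 below other genes here. Without Pathogen Only Liver replicate 2, which carried the gut transcripts, the medians of proteasome (0.56, adjusted p = 2.2e-06), neutrophil (0.42, adjusted p = 9.7e-04) and antigen presentation genes (0.42, adjusted p = 0.0044) were smaller, and that of sterol synthesis genes was -0.26 (adjusted p = 0.016). Without it the acute phase (median -0.04, adjusted p = 0.81) and hepatocyte (median 0.17, adjusted p = 0.55) differences were no longer past the threshold.

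A small set of liver genes was higher with both than with pathogen only, groups that also differ in pathogen dose. steap4 went from 29.4 ± 9.87 TPM with pathogen only to 340 ± 248 with both (log2 fold change 3.31, SE 0.45, adjusted p = 0.019), and tfpi2, a protease inhibitor, from 7.03 ± 1.99 to 89.5 ± 85.1 (3.12, SE 0.50, adjusted p = 0.041). The kinase mknk1 (2.30, SE 0.47), fyb2 (2.19, SE 0.41) and the bile acid-responsive hormone fgf19 (2.19, SE 0.41) rose. Proteasome genes lay above other genes (median 1.30, camera adjusted p = 2.7e-11, and adjusted p = 0.76 with an estimated correlation), and 24 of 30 passed adjusted over the list alone though none did over all genes. ER stress genes (median 1.01, adjusted p = 8.4e-10), complement genes (median 1.46, adjusted p = 8.2e-04) and NF-kB genes (median 0.61, adjusted p = 0.021) lay above as well. So did acute phase genes (median 0.86, adjusted p = 1.4e-05), hepatocyte genes (median 0.80, adjusted p = 2.6e-04) and sterol synthesis genes (median 0.97, adjusted p = 0.0077). Cell cycle genes (median -0.25, adjusted p = 1.9e-06) and neutrophil genes (median -0.23, adjusted p = 0.0077) lay below. With an estimated correlation NF-kB genes had adjusted p = 0.91, sterol synthesis genes adjusted p = 0.82 and the others adjusted p = 0.76. Adjusted over the list alone, 20 ER stress, 9 complement, 7 acute phase, 5 NF-kB, 5 sterol synthesis genes and 1 hepatocyte gene were higher. In the same way 1 complement gene and 1 cell cycle gene were lower.

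Members of those lists that did not pass over all genes included cfh, at 1874 ± 458 against 583 ± 379 TPM, and c9, at 2715 ± 1012 against 819 ± 875 TPM. Others were canx at 109 ± 30.7 against 41.7 ± 7.57 TPM, tnfaip3 at 29.0 ± 28.6 against 2.14 ± 2.15 and relb at 27.0 ± 27.3 against 2.32 ± 2.77. ahrr was at 1.94 ± 1.17 against 1.70 ± 2.74 TPM (adjusted p = 0.751). There were 35 calls, 33 higher and 2 lower, and 0 after median-of-ratios scaling (1770 at an unadjusted p under 0.05). With the level of cpb1 as a covariate 0 were called as well. Leaving out Pathogen Only Liver replicates 2, 3 and 1 gave 794, 228 and 0 calls, leaving out Oil and Pathogen Liver replicate 1 gave 115, and leaving out any of the other 8 liver libraries gave 1 to 14. Without Pathogen Only Liver replicate 1 neither steap4 (adjusted p = 0.071) nor tfpi2 (adjusted p = 0.101) passed. tfpi2 also did not pass without Control Liver replicates 2 (adjusted p = 0.065) or 3 (adjusted p = 0.062), Oil Only Liver replicate 3 (adjusted p = 0.057) or Oil and Pathogen Liver replicate 3 (adjusted p = 0.062). Without Pathogen Only Liver replicate 2 the complement (adjusted p = 0.78), acute phase (adjusted p = 0.99), hepatocyte (adjusted p = 0.80) and sterol synthesis lists (adjusted p = 0.78) were not past the threshold, the NF-kB median was 1.05, and 20 proteasome, 6 NF-kB, 3 ER stress and 2 complement genes and 1 gene each of the acute phase, hepatocyte and sterol synthesis lists rose while 1 cell cycle gene fell.

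Adding the pathogen to oil changed 3 liver genes. tfpi2 rose from 6.60 ± 1.70 to 89.5 ± 85.1 TPM (log2 fold change 3.20, SE 0.50, adjusted p = 0.035). The others carry locus numbers only: LOC104935027 rose from 0.748 ± 0.385 to 26.4 ± 22.3 TPM and LOC104934278 fell from 2461 ± 1179 to 297 ± 18.9. As a list, ER stress genes lay above other genes (median 0.57, camera adjusted p = 8.0e-20), as did NF-kB genes (median 0.49, adjusted p = 4.7e-07), both with adjusted p = 0.38 with an estimated correlation. Of the NF-kB genes, tnfaip3 (29.0 ± 28.6 against 1.86 ± 0.511 TPM) and rel (5.01 ± 2.59 against 0.921 ± 0.866 TPM) passed only adjusted over the list alone. Heat shock genes (median -0.53, camera adjusted p = 2.5e-05, and adjusted p = 0.52 with an estimated correlation) and oxidative stress genes (median -0.65, adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation) lay below other genes. No member of these 4 lists passed over all genes. Adjusted over the list alone, 1 ER stress gene was higher. The 1 oxidative stress gene that passed so, gpx7, was higher against the direction of its list (5.38 ± 2.15 against 1.06 ± 0.597 TPM). In all, camera placed 8 lists above and 6 below other genes here. ahrr was at 1.94 ± 1.17 against 1.79 ± 1.70 TPM. No gene was called after median-of-ratios scaling (679 at an unadjusted p under 0.05), and the counts of calls ran from 0 to 22 with 1 library left out, with tfpi2 between adjusted p = 0.0154 and adjusted p = 0.209.

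Across both pathogen states, oil raised fgf1 (log2 fold change 2.92, SE 0.50), dpp3 (2.73, SE 0.41), fgf19 (2.42, SE 0.29), the zinc transporter slc39a1 (2.39, SE 0.46) and steap4 (2.31, SE 0.32), comparing 6 with 6 liver libraries. The collagen gene col1a2 (-2.53, SE 0.50), the matrix proteoglycan lum (-1.91, SE 0.36), the caveolin cav1 (-1.76, SE 0.37), slc22a16 (-2.10, SE 0.27) and ccl17 (-1.41, SE 0.38) fell. All 10 also passed after median-of-ratios scaling. The pathogen groups with and without oil also differed in pathogen dose. Of 30 proteasome genes 28 rose (median 1.85, or 1.43 above all genes, camera adjusted p = 1.2e-15, and adjusted p = 0.92 with an estimated correlation), and 26 did after scaling. ER stress genes rose in 23 of 45 cases (median 0.84, adjusted p = 1.5e-04, and adjusted p = 0.92 with an estimated correlation), but in 1 case after scaling. Without Pathogen Only Liver replicate 2 that list was not past the threshold (adjusted p = 0.16). ahrr had a log2 fold change of 0.89 (adjusted p = 0.146). Of the 4 genes listed for the aryl hydrocarbon receptor, 1 other than ahrr rose, and 2 passed adjusted over the list alone.

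The main effect of oil called 2667 genes, 2484 higher and 183 lower, or 546 higher and 498 lower after scaling, and 0 with the level of cpb1 as a covariate. With 1 library left out it called 1599 and 1173 genes (Control Liver replicates 1 and 2), 1563 and 1312 (Oil Only Liver replicates 1 and 2), 1709 and 6260 (Pathogen Only Liver replicates 1 and 2), or 1252 and 1115 (Oil and Pathogen Liver replicates 2 and 3).

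The main effect of the pathogen and the interaction with oil gave no called gene in liver. For the main effect, limma found 812 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.097, and again called 0 after median-of-ratios scaling, with 1055. tfpi2 (log2 fold change 1.75, SE 0.35, adjusted p = 0.155), the clock gene bhlhe41 (1.52, SE 0.32, adjusted p = 0.167) and creld2 (2.36, SE 0.47, adjusted p = 0.188) had the smallest p-values with a symbol. ahrr had a log2 fold change of 0.54 (adjusted p = 0.875). ER stress genes (median 0.51, camera adjusted p = 1.4e-12) and neutrophil genes (median 0.63, adjusted p = 3.9e-06) lay above other genes, both with adjusted p = 0.35 with an estimated correlation. In all, camera placed 7 lists above and 9 below other genes for this main effect, and none passed with an estimated correlation. For the interaction, limma found 507 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.825, and 0 calls after scaling, with 533. There pdf (-2.16, SE 0.45), mknk2 (-2.27, SE 0.50) and tfpi2 (2.90, SE 0.70) had the smallest p-values, and ahrr was at -0.77 (adjusted p = 0.826). The pathogen was dosed higher with oil than alone, so the interaction also carries that difference.

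In spleen, fish given oil and pathogen had higher ahrr than control fish. ahrr, a repressor that the aryl hydrocarbon receptor induces, was at 62.8 and 44.0 TPM in the libraries given both, against 0 and 0.994 in control (log2 fold change 5.25, SE 1.18, adjusted p = 0.0029). rrad (6.42, SE 1.39), the macrophage gene gpnmb (5.58, SE 1.45), the antibacterial enzyme gene g-lysozyme (5.67, SE 1.43), steap4 (5.18, SE 1.47) and acod1, which makes itaconate in activated macrophages (4.80, SE 1.33), also rose. So did the sugar transporter slc2a6 (4.80, SE 1.29), tissue factor f3 (4.51, SE 1.27), tnfaip2 (5.30, SE 1.54), srgn (4.95, SE 1.28) and the prostaglandin synthase ptgs2 (3.16, SE 0.89). In the group given both, the SD exceeded the mean for g-lysozyme (1001 ± 1366 TPM), steap4 (1119 ± 1511), acod1 (544 ± 764), tnfaip2 (1179 ± 1449) and rrad (372.5 ± 421.8). It did so too for f3 (252 ± 347), slc2a6 (175.5 ± 228.6) and ptgs2 (17.7 ± 19.2), but not for ahrr, gpnmb and srgn. With n = 2, means with so large an SD came mainly from 1 library. acod1 was named through its list, and its libraries overlapped those of control. The median over all genes was 1.09 in this comparison. NF-kB genes lay above other genes (median 2.68, camera adjusted p = 1.2e-07, and adjusted p = 0.94 with an estimated correlation), with 3 of 36 rising and 9 passing adjusted over the list alone. Averaged over all its members, that list was at 4.44 and 6.04 log2(TPM + 1) in replicates 1 and 2 given both. Control Spleen replicates 1 and 2 were at 1.13 and 4.25. Neutrophil genes lay above too (median 3.30, adjusted p = 1.8e-07, and adjusted p = 0.83 with an estimated correlation), with 1 of 18 rising and 12 passing adjusted over the list alone. Proteasome genes had a median of 2.77 (adjusted p = 2.7e-05, and adjusted p = 0.94 with an estimated correlation), and none of 30 passed. Without the library labelled Control Spleen replicate 1, these medians were 1.09 (adjusted p = 3.5e-06) for NF-kB genes with 1 rising, 1.08 (adjusted p = 1.6e-06) for neutrophil genes with 2 rising and 1.64 (adjusted p = 1.1e-12) for proteasome genes. Of the 4 genes listed for the aryl hydrocarbon receptor ahrr rose, and 3 passed adjusted over the list alone.

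Genes made chiefly by hepatocytes were among the largest falls with a symbol in that spleen comparison, and the library labelled Control Spleen replicate 1 held them. The glycolytic gene gapdh fell most (-8.22, SE 1.54). fgg (-6.64, SE 1.41), serpinc1 (-6.46, SE 1.16), rbp4 (-6.39, SE 1.33), f2 (-6.11, SE 1.49) and ttr (-5.54, SE 1.16) fell, as did igfbp2 (-5.46, SE 1.11), serpinf1 (-4.67, SE 1.27) and the digestive enzyme gene amylase (-5.64, SE 1.56), which did not pass with any 1 spleen library left out. Of 16 hepatocyte genes 8 fell and of 14 acute phase genes 6 fell (camera adjusted p = 1.8e-43 and 2.3e-57, and adjusted p = 0.16 for both with an estimated correlation). There were 183 calls, 66 higher and 117 lower, over 14648 genes, and 0 after median-of-ratios scaling (1029 at an unadjusted p under 0.05, with ahrr at adjusted p = 0.40). That scaling divided the library labelled Control Spleen replicate 1 by 0.189 and the other spleen libraries by 1.06 to 1.71. The scaled fit of all 3 spleen comparisons carries this factor, so its counts are not a check free of that library. Leaving out Control Spleen replicates 1 and 2 gave 313 and 10378 calls, and leaving out Pathogen Only Spleen replicates 1 and 2 or Oil and Pathogen Spleen replicates 1 and 2 gave 2, 10, 30 and 4. Without the library labelled Control Spleen replicate 1, ahrr (4.75, adjusted p = 1.2e-08), rrad, gpnmb, ptgs2, gapdh, serpinc1, rbp4, igfbp2 and serpinf1 passed. The genes g-lysozyme, steap4, acod1, tnfaip2, slc2a6, f3, srgn, fgg, f2, ttr and amylase did not pass there. In that fit 3 hepatocyte and 2 acute phase genes fell and 1 hepatocyte gene rose. ahrr did not pass without Pathogen Only Spleen replicate 1 (adjusted p = 0.192) or 2 (adjusted p = 0.223), or without Oil and Pathogen Spleen replicate 1 (adjusted p = 0.193) or 2 (adjusted p = 0.479).

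**Figure D3:**
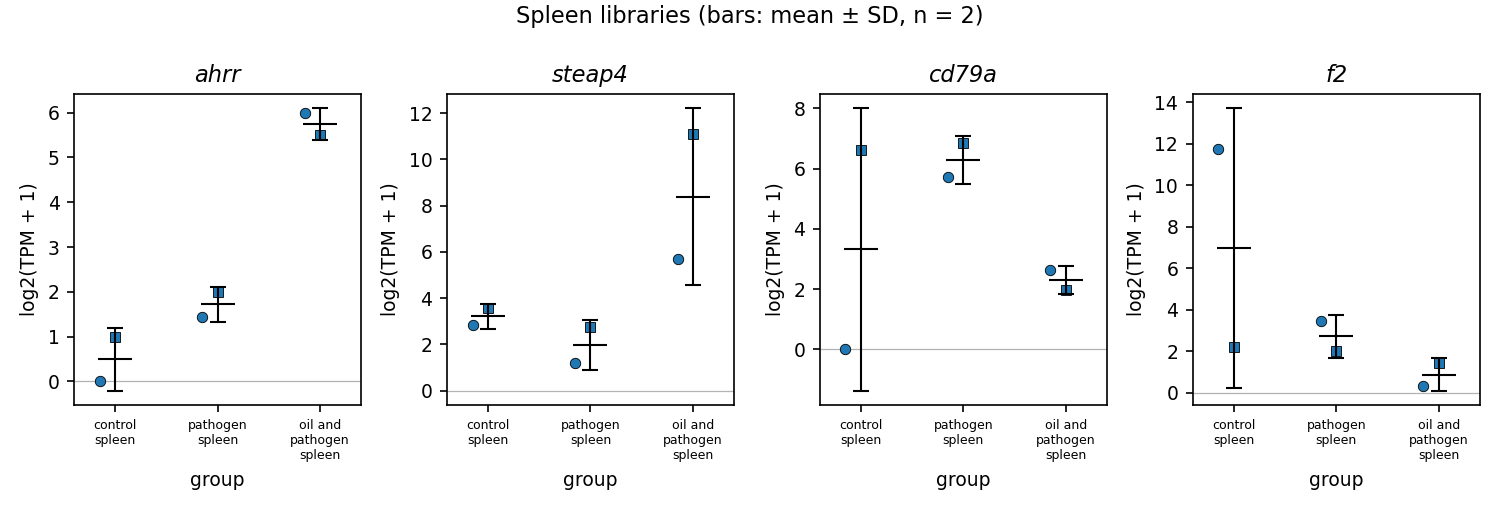
log2(TPM + 1) of ahrr, steap4, cd79a and f2 in each spleen library, by group. Symbols are libraries (circle replicate 1, square replicate 2) and bars the group mean ± SD (n = 2); the control library with cd79a at 0 and the highest f2 is the one labelled Control Spleen replicate 1.

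Genes made chiefly by hepatocytes were among the falls in pathogen only against control spleen, and the library labelled Control Spleen replicate 1 held them. fgg (-5.77, SE 1.41), serpinc1 (-5.84, SE 1.16), ttr (-4.94, SE 1.16), igfbp2 (-4.26, SE 1.11) and gapdh (-5.96, SE 1.54) fell, as did the amino acid transporter slc7a9 of kidney and gut (-3.63, SE 0.79). The kidney salt transporter slc12a1 fell from 57.1 ± 78.9 TPM in control and was listed at 0 in both pathogen libraries. Without the library labelled Control Spleen replicate 1, 2 hepatocyte genes and 1 acute phase gene fell, fgg and ttr no longer passed and serpinc1, igfbp2, gapdh, slc12a1 and slc7a9 did. Of 16 hepatocyte genes 4 fell and of 14 acute phase genes 4 fell, or 13 and 12 adjusted over the list alone (camera adjusted p = 3.1e-56 and 1.0e-80, and adjusted p = 0.10 for both with an estimated correlation). ahrr was at 2.36 ± 0.890 TPM (SD, n = 2) against 0 and 0.994 in the control libraries (adjusted p = 0.78). There were 47 calls, 46 lower and 1 higher with a locus number only, and 0 after median-of-ratios scaling (219 at an unadjusted p under 0.05). Leaving out Control Spleen replicates 1 and 2 gave 79 and 9799 calls, and leaving out any of the other 4 spleen libraries gave 0.

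In spleen, steap4 was at 1119 ± 1511 TPM with both against 3.48 ± 3.08 with pathogen only (log2 fold change 6.42, SE 1.47, adjusted p = 0.016). g-lysozyme (6.11, SE 1.43) and rrad (5.67, SE 1.39) were higher too. For all 3 genes the SD in the group given both exceeded the mean. That group also had the higher pathogen dose, and no oil only spleen group was analysed. Oil and dose cannot be told apart in this comparison. NF-kB genes lay above other genes (median 1.56, camera adjusted p = 3.5e-08, and adjusted p = 0.94 with an estimated correlation, as for the other 4 lists named here), with ptgs2 at 17.7 ± 19.2 against 0.553 ± 0.0553 TPM and fosl1 at 28.6 ± 33.7 against 1.32 ± 1.16. Averaged over all its members, the NF-kB list was at 4.44 and 6.04 log2(TPM + 1) in replicates 1 and 2 given both. With pathogen only it was at 3.47 and 4.22, so most of its rise lay in Oil and Pathogen Spleen replicate 2. Neutrophil genes lay above too (median 1.12, adjusted p = 9.5e-06), with lcn2 at 150 ± 50.4 against 3.93 ± 3.65 TPM, alox5ap at 193 ± 153 against 17.8 ± 13.4 and mmp9 at 65.9 ± 78.0 against 6.84 ± 4.75. So did proteasome genes (median 1.76, adjusted p = 7.0e-08) and oxidative phosphorylation genes (median 1.16, adjusted p = 3.8e-04). B cell genes lay below (median -1.05, adjusted p = 1.1e-05), with cd79a at 4.10 ± 1.62 against 82.9 ± 44.1 TPM and tnfrsf13b at 1.88 ± 0.365 against 25.5 ± 20.3. The B cell regulators pou2af1 (3.62 ± 1.81 against 26.4 ± 12.3 TPM) and pax5 (0.0617 ± 0.0872 against 3.38 ± 1.52 TPM) were measured with them. Over all genes no member of these 5 lists passed. Adjusted over the list alone, 3 NF-kB genes and 1 neutrophil gene were higher and 2 B cell genes lower. Without the library labelled Control Spleen replicate 1, 10 NF-kB, 7 proteasome and 4 neutrophil genes and 1 B cell gene rose, and 5 B cell genes and 1 NF-kB gene fell.

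ahrr was at 53.4 ± 13.3 TPM in spleen given both against 2.36 ± 0.890 with pathogen only (SD, n = 2 each, log2 fold change 4.02, SE 1.18, adjusted p = 0.20), and tiparp at 94.7 ± 27.8 against 21.3 ± 7.78. gpnmb was at 190 ± 95.3 against 11.5 ± 3.39 TPM. There were 23 calls, 20 higher and 3 lower, of which 20 carry locus numbers only, and 0 after median-of-ratios scaling (427 at an unadjusted p under 0.05). The control libraries enter this comparison through the shared estimate of spread. Leaving out Control Spleen replicates 1 and 2 gave 638 and 647 calls, leaving out Pathogen Only Spleen replicates 1 and 2 gave 0 and 14, and leaving out Oil and Pathogen Spleen replicate 2 gave 4. The calls without the library labelled Control Spleen replicate 1 took in ahrr (adjusted p = 2.7e-09, or 0.12 with scaling as well), tiparp, gpnmb, lcn2, ptgs2, fosl1, alox5ap, mmp9, rrad, cd79a, pax5, tnfrsf13b and pou2af1, but not steap4 and g-lysozyme. steap4 passed with 1 library left out only without Oil and Pathogen Spleen replicate 1 (adjusted p = 0.0329).

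The pathogen effect was not shown to differ between spleen and liver for any gene. limma called 0 of 15784 genes for the difference, with 512 at an unadjusted p under 0.05 and a smallest adjusted p of 0.063, and 1 lower gene after median-of-ratios scaling, with 1184. tm4sf5 (difference of log2 fold changes -4.60, SE 0.83, adjusted p = 0.151), the receptor sigirr (-3.64, SE 0.71, adjusted p = 0.182) and the hepatic transcription factor creb3l3 (-3.59, SE 0.82, adjusted p = 0.43) had the smallest p-values with a symbol. ahrr had a difference of 0.30 (adjusted p = 0.925). No call was shared between the tissues, liver having none. The pathogen fold changes correlated across 11287 genes, which are not independent replicates, at 0.134 (Pearson) and 0.170 (Spearman). Leaving out Control Spleen replicates 1 and 2 gave 23 and 7344 calls, leaving out Pathogen Only Liver replicate 2 gave 5, and leaving out any of the other libraries gave 0 or 1. tm4sf5 and sigirr passed without either control spleen library, but each of these fits holds 1 control spleen library. Without replicate 2 that library is the one with the liver-like profile, so passing there cannot weigh the pathogen effect.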

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

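All tests of explanations in this part were chosen after the results were seen. Gene lists were taken up here where camera's test of a difference between effects passed, that is, the difference of the pathogen effect between spleen and liver or the interaction of oil and pathogen in liver. Medians are of log2 fold change differences.

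For the difference between tissues (spleen minus liver), 10 lists lay below other genes and 5 above. Below, acute phase genes had a median of -3.79, hepatocyte genes -2.87, muscle, adipose and gut genes -2.88, glucose metabolism -1.07, complement -0.92, other detoxification genes -0.67 and fatty acid oxidation -0.46. Oxidative phosphorylation (-0.28), ribosomal proteins (-0.27) and steroid, stress, thyroid and estrogen genes (-0.18) also lay below. Above other genes, the medians were 1.67 for B cells, 1.60 for thrombocytes and endothelium, 1.33 for erythroid cells, 1.285 for T and NK cells and 0.83 for the cell cycle. With an estimated correlation, glucose metabolism (adjusted p = 0.0258) and muscle, adipose and gut genes (adjusted p = 0.0350) passed and the others did not. Without the library labelled Control Spleen replicate 1 these medians were -0.54 (adjusted p = 0.891) and -0.57 (adjusted p = 0.562). The medians of all 15 lists then lay between -0.77 and -0.04, and 3 lists passed: thrombocytes and endothelium above other genes (-0.14, adjusted p = 0.0075), and ribosomal proteins (-0.67, adjusted p = 2.1e-04) and oxidative phosphorylation (-0.77, adjusted p = 3.7e-04) below. With all libraries of replicate number 1 left out, acute phase and hepatocyte genes passed in the other direction (adjusted p = 0.0365 for both).

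The library labelled Control Spleen replicate 1 had a liver-like profile, with hepatocyte markers at 6.53 log2(TPM + 1) and f2 at 3423 TPM. Its highest Spearman correlation with a liver library was 0.837, below the lowest value between liver libraries (0.860). The kidney transporter slc12a1, at 57.1 ± 78.9 TPM in control spleen (SD, n = 2), was not used to weigh another organ. A swap with a liver library of the series is argued against, since 0 liver libraries were closer to spleen than to liver. Spleen mixed with liver is argued against too, since spleen-typical features lay at a median of 0.769% of the lowest other spleen library. A wrong label or another organ in the sample could account for it and stays open: 28.8% of liver-typical features reached the level of the lowest liver library, and 8.47% lay below 0.1 of it. A biological explanation was not tested.

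In the liver interaction, sterol synthesis genes (0.98), complement (0.57), acute phase genes (0.52), hepatocyte genes (0.35), ER stress genes (0.27) and NF-kB genes (0.078) lay above other genes. Iron handling genes were placed above too although their median was -0.14 and their mean 0.06, since the median of all genes was -0.40. Proteasome genes (-1.14), heat shock genes (-1.03) and oxidative phosphorylation genes (-0.51) lay below. None passed with an estimated correlation, where sterol synthesis and complement had adjusted p = 0.402, acute phase genes adjusted p = 0.807, and proteasome and heat shock genes adjusted p = 0.815. Without Pathogen Only Liver replicate 2, acute phase (median -0.09, adjusted p = 0.696), complement (median 0.11, adjusted p = 0.153), hepatocyte (median -0.21, adjusted p = 0.153) and iron handling genes (median -0.04, adjusted p = 0.659) were not past the threshold. With all libraries of replicate number 2 left out, hepatocyte genes passed in the other direction (adjusted p = 0.0207). The other medians without Pathogen Only Liver replicate 2 were -0.75 for proteasome, -0.72 for heat shock, -0.33 for oxidative phosphorylation, 0.58 for NF-kB, 0.14 for ER stress and 0.87 for sterol synthesis genes. The pathogen dose also differed between the groups with and without oil.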

How the results depend on the processing

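Quantile normalization, sample quality weights, the cpb1 level as covariate, scaling combined with it or with fewer groups, and settings that combine scaling with a library left out were chosen after the data were seen; the other alternatives were fixed before. The alternatives planned with DESeq2 and voom were not run because the values are not counts. TPM holds no depth, so a limit set by depth cannot be given. Where a count changed with a setting, the cause was not tested, except that settings with fewer libraries or groups have fewer residual degrees of freedom. A spleen group with a library left out holds 1 library, which is assumed to vary like the other groups. Without Control Spleen replicate 2 the only control spleen library is the one with the liver-like profile. Counts of that setting thus set spleen against a liver-like library.

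Counts of called genes follow in the order oil only against control, both against control, both against pathogen only and both against oil only in liver, the main effect of oil, the spleen comparisons (pathogen only against control, both against control, both against pathogen only) and the tissue difference. Comparisons not named stayed within 1.5 times of their count. The counts to compare with are 1415, 1205, 35, 3, 2667, 47, 183, 23 and 0. A pseudocount of 0.1 gave 5 for both against oil only, 0, 0 and 0 in spleen and 21 for the tissue difference. A pseudocount of 5 gave 803 for both against control, 1 for both against pathogen only and 0 for both against oil only. No filter gave 339, 390, 0, 0, 1604, 0, 0, 0 and 7. A filter of 5 TPM gave 56 for both against pathogen only, 5 for both against oil only, and 11, 86 and 11 in spleen. Median-of-ratios scaling gave 168, 168, 0, 0, 1044, 0, 0, 0 and 1. Fits of only the groups compared gave 4362, 3625, 3 and 12 in liver and 0, 5 and 648 in spleen, the last of which was 0 with scaling as well. Quantile normalization gave 133, 176, 0, 0, 1073, 0, 0, 0 and 1. Sample quality weights gave 5937, 6134, 0, 107, 5303, 3, 19 and 697. The cpb1 level as covariate gave 0, 0, 0, 6, 0, 71, 11, 49 and 6, and with scaling 0, 1, 0, 0, 0, 0, 0, 0 and 1. Scaling without Pathogen Only Liver replicate 2 gave 673, 783, 0, 14 and 1607. At an adjusted p under 0.01, 41 higher and 3 lower calls were shared between oil only and both, against 666 and 27.

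With 1 library left out, counts ran from 61 to 4271 for oil only against control, 0 to 2 for pathogen only against control, 18 to 3480 for both against control, 0 to 794 for both against pathogen only and 0 to 22 for both against oil only in liver. They ran from 0 to 1 for the interaction, 1115 to 6260 for the main effect of oil and 0 to 8 for that of the pathogen. In spleen they ran from 0 to 9799, 2 to 10378 and 0 to 647, and for the tissue difference from 0 to 7344.

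The replicate number as a block gave 23 calls for both against pathogen only and 13 for both against oil only in liver, 3 for the main effect of the pathogen and 44 for both against pathogen only in spleen, and stayed within 1.5 times elsewhere. In neither tissue did every pair with the same number correlate above 0.1, so the samples were not treated as paired. In liver 2 of 18 pairs with the same number had deviations correlated above 0.1 (from -0.173 to 0.235), and 3 of 12 libraries correlated best with their own number. In spleen 4 of 6 pairs did (from -0.0414 to 0.387), and 6 of 6 libraries correlated best with their own number, a hint from the data, not the design, that the numbers may be shared there.

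Camera called 141 lists in 333 tests, of which 2 were left with an estimated correlation; scaling gave 136 and the replicate block 141. Fry called 37, not all of them called by camera. Of these, 12 were in oil only against control, 10 in both against control and 15 in the main effect of oil, with none elsewhere. Proteasome genes were among them each time (fry adjusted p = 0.0062, 0.013 and 0.0046). Fry gave the other direction, not past the threshold, for sterol synthesis (adjusted p = 0.844), cell cycle, neutrophil and interferon genes (adjusted p = 0.885) in oil only against control, cell cycle genes (adjusted p = 0.630) in both against control, and iron handling genes (adjusted p = 0.858) in the interaction. Fry asks which way a list itself moves, and camera whether it lies above other genes. Scaling reversed oxidative phosphorylation in oil only against control (adjusted p = 0.866). With all libraries of replicate number 1 left out, lists reversed in the tissue difference, over adjusted p values of 1.5e-14 to 0.764 for glucose metabolism, 3.2e-41 to 0.0365 for acute phase, 9.0e-11 to 0.0528 for complement, 7.2e-39 to 0.0365 for hepatocyte, 8.3e-11 to 0.692 for fatty acid oxidation, 4.2e-14 to 0.0985 for ribosomal proteins and 4.5e-06 to 0.692 for steroid, stress, thyroid and estrogen genes. In the interaction oxidative phosphorylation did (3.1e-05 to 0.358). With number 2 left out, the reversals were hepatocyte (3.3e-15 to 0.50) and acute phase genes (3.5e-20 to 0.963) in pathogen only against control liver. Acute phase (7.8e-14 to 0.924) and hepatocyte genes (2.3e-08 to 0.0207) also reversed in the interaction, and hepatocyte genes in the main effect of oil (5.5e-04 to 0.897). Of these, acute phase and hepatocyte genes in the tissue difference and hepatocyte genes in the interaction passed in the other direction, and the others did not. Over all lists outside the spleen comparisons, 79 to 99 passed, against 95. Number 1 takes out the control spleen library with the liver profile and number 2 the pathogen only liver library with gut transcripts.

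Single values named in the text, outside leaving out libraries, kept their side of the threshold in 1163 cases, became weaker in 564, stronger in 48 and changed sign without passing in 6. Only cpb1 (0) and pglyrp2 (0.044) in oil only against control changed direction, both with cpb1 as covariate, which sets cpb1 to 0 by construction. With a library left out 1194 were the same, 381 weaker and 44 stronger, 7 changed sign without passing, and 0 reversed. Lists gave 173 the same, 138 weaker, 5 stronger and 1 with another sign without passing, and with a replicate number left out 145 the same, 30 weaker and 4 stronger. Marker levels as medians of members lay within 1 SD of the group from the mean of members in 31 cases and outside it in 32.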

Other observations

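All tests of explanations in this part, the counts over other splits of the libraries included, were chosen after the results were seen.

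The differences between groups given both and pathogen only, which also differ in pathogen dose, were compared between spleen and liver. Across 11287 genes, which are not independent replicates, the log2 fold changes of both against pathogen only correlated at 0.376 (Pearson) and 0.357 (Spearman) between the tissues. steap4, a metalloreductase of iron uptake, was the 1 gene called higher in both. In spleen it was at 1119 ± 1511 TPM and passed in 1 of the 6 fits with 1 library left out. After median-of-ratios scaling limma called 0 genes in either tissue, with 1770 in liver and 427 in spleen at an unadjusted p under 0.05. LOC104920743, which rose with oil in liver, was at 1306 ± 122 TPM in spleen given both against 8.78 ± 2.34 with pathogen only (SD, n = 2 each).

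Lists of immune genes and of ER stress also lay apart in spleen given both against pathogen only. Interferon genes (median 1.16, camera adjusted p = 5.0e-04), antigen presentation genes (median 1.36, adjusted p = 0.0060) and ER stress genes (median 1.05, adjusted p = 0.0015) lay above other genes. T and NK cell genes lay below (median -0.50, adjusted p = 0.0096). All 4 had adjusted p = 0.94 with an estimated correlation and no member passed. Without the library labelled Control Spleen replicate 1, 5 interferon, 3 ER stress genes and 1 antigen presentation gene rose and 1 T and NK cell gene fell. Macrophage genes in spleen given both against control had a median of 2.03, with 1 of 14 rising (adjusted p = 0.0266, and adjusted p = 0.94 with an estimated correlation), and a median of 0.28 without the library labelled Control Spleen replicate 1. In liver, 9 of 22 hepatocyte genes rose with the main effect of oil (median 0.80, adjusted p = 0.0428, and adjusted p = 0.92 with an estimated correlation), and none did after median-of-ratios scaling. Without Pathogen Only Liver replicate 2 that list had a median of 0.51 and adjusted p = 0.99.

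The calls in oil only liver were one-sided and took in 28 of 30 proteasome genes. Composition on the TPM scale is argued against as the whole cause of the proteasome rise, since 15 members passed after scaling, with a median of 1.68. A smaller share of pancreas is also argued against as the whole cause, since the proteasome median exceeded that of hepatocyte genes by 1.83, beyond their larger SD of 0.882. A trend with cpb1, which would stand for pancreas in the sample, stays open beside an effect of oil: with it as covariate the median was 2.01 (SE 0.686, before 2.45, SE 0.439) and 0 members passed; the SE grew, and 65.3% of the variance of cpb1 lay between groups. Composition also stays open for the one-sided split: after scaling 61.3% of calls were higher, against 94.8% before, but the scaling centres the genes and so evens the split whatever its cause.

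Few genes were called between liver given both and pathogen only. Gut transcripts in Pathogen Only Liver replicate 2 could lower the count by widening the spread: without that library 794 genes were called on the TPM scale but 0 after scaling, so this stays open. Composition on the TPM scale is argued against as a reason for few calls, since scaling gave 0 calls against 35. A response that differs little between these groups was not tested apart from the higher pathogen dose given with oil.

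Other splits of the same libraries were counted. With 3 against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1415 and 0 for oil only against control, 0 and 0 for pathogen only against control, 1205 and 5 for both against control, 35 and 2 for both against pathogen only and 3 and 0 for both against oil only. For the main effect of oil, 1 of 100 regroupings, the real one, gave as many calls (2667, highest other 1190), a share of 0.01. For the main effect of the pathogen, also 6 libraries against 6, the same regroupings reached 4589 and 3951 calls. A regrouping can thus exceed 2667, so the share of 0.01 does not rule out chance. For the interaction and the main effect of the pathogen the real count was 0, so all 100 regroupings gave as many by definition and the count decides nothing. The highest other was 20 for the interaction. For the main effect of the pathogen it was 4589, which points to a structure of the samples. That regrouping had 5 of the 6 oil-exposed libraries on 1 side, and 7 of the 13 regroupings split that way called any gene, against 2 of the other 86, with at most 2 calls. Most of these calls thus came with 5 oil-exposed libraries on 1 side, although 6 of the 13 called 0. The highest counts, 4589 and 3951, exceeded the 2667 of the real split by oil. Oil exposure alone therefore does not set the count, and what else does was not tested.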
